A study of Homo sapiens with 8 samples.

How the data were processed

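Total RNA of SNB-19 and U-87MG glioma cells, taken 36 h after transfection with a miR-30e* mimic or a negative-control mimic, was labelled with Cy3 and hybridised to 8 1-colour Agilent arrays, per the labels' protocols. The labels put the arrays in 4 groups of 2 biological replicates. Per the file headers, the scanner images were read with Agilent Feature Extraction 10.5.1.1 on array design 014850, whose grid was built on hg18. Per the file headers, the deposited intensity values are background-subtracted and spatially detrended spot signals, not normalized between arrays. The deposited value table of the whole series holds log2 values. Set against the scanner signals, these were scaled to each array's 75th percentile and centred on each probe's median over the arrays, with column medians of -0.0159, -0.0638, -0.0351, -0.0580, 0.0530, -0.0154, 0.0931 and 0.0570. Its scale and centring were found this way; its labels of control and mimic are exchanged relative to the scanner files, and which are right stays unknown. The scanner files, with their own labels, gave all main values.

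From the scanner files, control spots (1639 of 45015 per array) and spots with an outlier flag (0.182% to 0.733%) were left out, and spots of 1 probe were averaged. The processed signal was log2-transformed and each array's 75th percentile subtracted. The 75th percentile lay between 11.08 and 11.64 and the median local background between 5 and 5.23 on the log2 scale. Of 41000 probes, 26816 carried a RefSeq accession and 25398 (61.9%) were given a current symbol through the RefSeq gene table of assembly GRCh38.p14, for 17240 distinct symbols. Because that assembly differs from the array's build, no coordinates are given. The other 15602 probes were counted without being named. A probe was used if it was well above background on both arrays of at least 1 of the 4 groups, which 32304 probes were. A gene was represented by its probe with the highest mean over the 8 arrays, leaving 24861 genes, 10175 of them transcripts without a symbol, and 526 with a value missing on at least 1 array. Probes of the same gene were called in opposite directions for 144 genes in SNB-19, 190 in U-87MG and 195 in the mean effect.

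Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 8 arrays (4 residual degrees of freedom), empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The 5 comparisons were mimic against control in each line, their mean, their difference, and U-87MG against SNB-19 on the control arrays. Where the probe that represents a gene was not well above background on either array of a group, the fold is given as "at least", and a gene is called below background only if all its probes were so. It is the brighter group's mean against the mean, over the dim group's arrays, of the higher of the dim probe's own signal and the lowest signal among probes well above background. Such a bound holds for the main processing only, and changes under another background correction can be smaller than it. The 13 gene lists, fixed from textbook knowledge before the data were examined, were NF-kB targets, type I interferon response, proteases with adhesion and angiogenesis, mitosis, DNA replication, cholesterol, endoplasmic reticulum and amino acid stress, hypoxia, p53 targets, TGF-beta and mesenchymal genes, miRNA pathway proteins, glial and neural progenitor genes, and markers of other cell types. VEGFA stands in 3 of them. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. With an estimated correlation camera also refers its statistic to the 4 residual degrees of freedom, which alone raises p. A call lost there is therefore not due to the correlation alone. The NF-kB and interferon lists held their calls with an estimated correlation in each line and in the mean, and the mitotic and cholesterol lists in SNB-19; all other list calls were lost.

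Except for the family members under other observations, chosen after the data were seen, the genes named in the text followed a rule set before the data were examined. They were NFKBIA and NFYC, and in each comparison the 10 (8 for the difference and for the lines) largest changes each way among called genes with a symbol whose groups did not overlap. For each list, the 4 members with the smallest p in the mean effect were added. XIST and Y-linked genes were left out. Some genes that the rule picked are not reported here; counts over the picked genes include them. Alternatives covered the background correction (normexp, offset 50), quantile and median scaling, the filter, the value table, the treatment of several probes per gene, the arrays in the fit, an intensity trend, the replicate number as a block and each array left out; the files hold no mean signal column, so normexp used the median signal and median background. The slide as a block was not fitted as an alternative, because slide and line coincide and the effects are already within a slide.

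The tests were checked on simulated data for 24335 genes, drawn with 1 normal spread per gene, the same in all 4 groups. On the real arrays replicates differed most in the U-87MG mimic group. Far fewer genes were changed in the simulation than were called in the 3 comparisons below (38.6% to 48.8% of genes). The simulated counts therefore do not give the false-call rate of the real comparisons. In the SNB-19 comparison limma called 11 of 50 genes changed 1.5-fold, 35 of 50 at 2-fold, 49 at 4-fold and 50 at 8-fold, with 7 false calls. In the U-87MG comparison it called 14, 39, 49 and 50, with 12 false calls, and in the mean effect 32, 42, 49 and 50, with 13. Of 50 genes changed 4-fold in U-87MG alone, the test of the difference called 45. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.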

Results

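The series measured gene expression in 2 human glioma cell lines, SNB-19 and U-87MG, 36 h after lipid transfection with a synthetic mimic of miR-30e* or with a negative-control mimic. miR-30e* is the microRNA cut from the 3′ arm of the miR-30e hairpin, and both lines are long-established cultures of human malignant glioma. Each of the 4 groups had 2 biological replicates, and each of the 8 RNA samples was read on its own 1-colour Agilent whole-genome array. Between 72.8% and 78.9% of the 41000 probes were well above background on an array, and 0 spots were saturated. Replicate arrays correlated at r = 0.993 to 0.998 across probes, which are not independent replicates. The SD of the log2 difference between replicates was 0.385 in the U-87MG mimic group, and 0.192, 0.209 and 0.251 in the SNB-19 mimic, SNB-19 control and U-87MG control groups. The tests covered 24861 genes, of which 14686 had a gene symbol. With 2 arrays per group, the number of arrays limits the precision of every value. All SNB-19 arrays lay on 1 slide and all U-87MG arrays on another, so line and slide cannot be told apart. On each slide the arrays labelled control took positions 1 and 2 and those labelled mimic positions 3 and 4, so treatment and position cannot be told apart either.

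The labels of the deposited files contradicted each other on treatment. Each of the 8 columns of the submitters' value table matched the scanner file of the other treatment, of the same line and replicate number, with a correlation of at least 0.9999 across probes. Its correlation with the scanner file of its own label was between -0.159 and 0.024. Which labels are right was not settled here. All directions below follow the labels of the scanner files, and "mimic" and "control" stand for arrays so labelled. If the scanner values are given the value table's labels, every direction of a mimic effect turns, and counts of higher and lower genes change places. The value table's own values give somewhat different counts, stated in the part on processing.

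The first comparison asked which genes the mimic changed in SNB-19. Interferon-response and chemokine genes were among the largest increases on the arrays labelled mimic, and mitotic and cholesterol genes were lower as lists. The antiviral genes XAF1 (178-fold), RSAD2 (148-fold) and MX1 (74.8-fold) rose most among the interferon-response genes. CXCL11, CXCL10 and CCL20, which encode chemokines, rose 128-fold, 106-fold and 71.0-fold, and CSF3, the granulocyte colony-stimulating factor gene, rose 90.3-fold. In all, 5419 genes were higher and 6304 lower among 24857 tested (limma, 2 arrays per group, adjusted p under 0.05), or 6304 higher and 5419 lower with the labels turned. Of these, 1713 and 1808 changed by at least 2-fold. The SE of the log2 change was 0.0762 to 0.725 among the 20 largest changes picked by the naming rule, all with an adjusted p of at most 0.00164.

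NFKBIA, which encodes the NF-kB inhibitor IkB-alpha and has been proposed as a target of miR-30e*, was higher by 1.03 ± 0.0925 (log2, SE, limma adjusted p = 0.000303). This is opposite to the decrease expected if the mimic lowered NFKBIA mRNA, but NFKBIA is itself in the NF-kB target list, and no test here shows whether its mRNA or translation was repressed; under the value table's labels NFKBIA was lower, with a log2 change of -1.04. NFYC, the host gene of the miR-30e hairpin, had a log2 change of 0.13 ± 0.0944 (adjusted p = 0.321). Besides the genes above, the long non-coding RNA gene UCA1 rose 56.1-fold. The hair keratin-associated gene KRTAP1-5 rose at least 80.1-fold and the anion transporter gene SLCO2B1 at least 14.0-fold, both from below background. On the lower side, the chemokine gene CXCL14 fell 41.7-fold, the matricellular gene SPARCL1 25.7-fold, C6orf15 23.2-fold and the G-protein signalling regulator RGS16 22.9-fold. POSTN (periostin), PLEKHS1, PLXDC2, FLT3 (a receptor tyrosine kinase), BBOX1 (carnitine synthesis) and RGMA (an axon guidance protein) fell to below background. Their decreases were at least 12.1-fold, 10.8-fold, 9.31-fold, 9.19-fold, 7.69-fold and 6.05-fold. Under normexp their log2 changes were smaller than these bounds, from -1.994 for POSTN to -1.312 for RGMA.

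Of the 13 gene lists fixed before the data were examined, 4 were higher and 3 lower in SNB-19 by camera. All 30 measured type I interferon response genes rose, also when adjusted over the list alone, with a mean log2 change of 3.7 (camera adjusted p = 1.45e-24; adjusted p = 0.0343 with an estimated correlation). MX2 rose 42.2-fold and OASL 27.8-fold in this list. Of 35 measured NF-kB target genes, 30 rose and 1 fell (32 and 1 adjusted over the list alone), with a mean of 1.84 (adjusted p = 9.95e-15; adjusted p = 0.0465 with an estimated correlation). The interleukin gene IL1B rose 11.4-fold, CXCL1 7.34-fold and CSF2 6.55-fold. Among 33 matrix protease, adhesion and angiogenesis genes, 13 rose and 5 fell, over the list alone too. The mean was 0.916 and the median 0.269 (camera adjusted p = 0.0019, or 0.175 with an estimated correlation). Its increases included those of the matrix metalloprotease genes MMP3 (51.7-fold), MMP1 (11.4-fold), MMP13 (9.30-fold) and MMP9 (4-fold). Of 27 endoplasmic reticulum and amino acid stress genes, 14 rose and 3 fell, over the list alone too (mean 0.351, adjusted p = 0.00319; adjusted p = 0.237 with an estimated correlation). CEBPB, a transcription factor gene, rose 2.56-fold, PPP1R15A 2.38-fold and the chaperone gene HSPA5 1.36-fold, and the serine synthesis gene PHGDH fell 1.41-fold.

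Of 30 mitotic cell cycle genes, 28 fell and 0 rose (29 and 0 adjusted over the list alone), with a mean of -0.803 (adjusted p = 3.1e-10; adjusted p = 0.0465 with an estimated correlation). The phosphatase gene CDC25C fell 3.30-fold, the checkpoint kinase gene BUB1 2.75-fold, the kinesin gene KIF20A 2.63-fold and PRC1 1.93-fold. Of 25 cholesterol synthesis and uptake genes, 23 fell and 0 rose (24 and 0 over the list alone), with a mean of -1.0 (adjusted p = 1.92e-09; adjusted p = 0.0465 with an estimated correlation). MVK, the mevalonate kinase gene, fell 3.51-fold, MSMO1 3.48-fold and DHCR7 2.12-fold. Of 22 glial and neural progenitor genes, 12 fell and 3 rose (13 and 3 over the list alone), with a mean of -0.625 (adjusted p = 0.00319; adjusted p = 0.0949 with an estimated correlation). The brain fatty-acid-binding protein gene FABP7 fell 7.99-fold, S100B 6.72-fold, SOX2 3.57-fold and PDGFRA 3.34-fold. The other 6 lists were not called, with adjusted p of 0.0716 for DNA replication (4 rose and 15 fell of 34) and 0.201 for markers of other cell types (5 and 2 of 19). For TGF-beta response and mesenchymal genes (13 and 8 of 35, adjusted p = 0.259), camera and the mean of 0.132 pointed up and the median of -0.02 down. Hypoxia (7 and 6 of 27), p53 targets (4 and 8 of 25) and miRNA pathway proteins (6 and 2 of 14) each had an adjusted p of 0.292. Under normexp background correction 2043 genes were higher and 1991 lower, and 7 of the 21 named genes above lost the call (SLCO2B1 and the 6 that fell below background). RGMA also lost it with no filter on dim probes (log2 change of -0.12, adjusted p = 0.772), where a probe that had failed the filter stood for the gene. The DNA replication list was called lower under quantile normalization (adjusted p = 0.0358) and normexp (adjusted p = 0.0175).

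**Figure D1:**
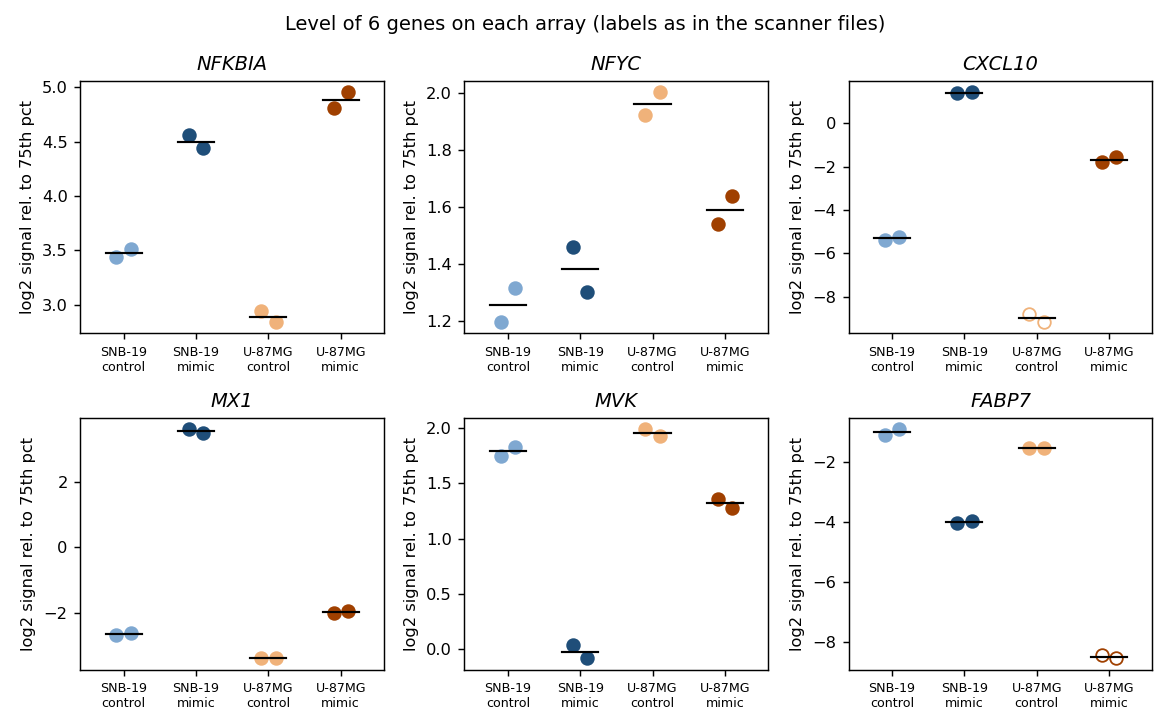
Level of 6 genes on each of the 8 arrays (vertical axes, log2 signal minus the array's 75th percentile, each panel with its own range), by group as labelled in the scanner files. Points are arrays, bars are means of 2 arrays, and open points were not well above background. NFKBIA, CXCL10 and MX1 lay higher and MVK and FABP7 lower on the arrays labelled mimic in both lines, directions that turn under the value table's labels, while the NFYC change passed the test in U-87MG only (adjusted p = 0.0241).

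The same question in U-87MG gave large increases of cytokine and chemokine genes on the arrays labelled mimic, and decreases below background of genes such as NFIB and POU3F2. CSF3 rose 453-fold, the chemokine gene CXCL1 98.6-fold, the complement gene C3 89.5-fold, the serum amyloid gene SAA1 75.4-fold and the protease gene MMP3 52.2-fold. CCL20 rose at least 97.4-fold and CXCL10 at least 34.2-fold from below background. CXCL14 fell at least 1990-fold, to below background. In all, 3637 genes were higher and 5963 lower among 24857 tested (limma, 2 arrays per group), or the reverse with the labels turned, and 595 and 1533 of them changed by at least 2-fold. The SE was 0.09 to 0.512 among the 20 largest changes picked by the naming rule, all with an adjusted p of at most 5.5e-05.

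NFKBIA was higher by 1.99 ± 0.0925 (adjusted p = 3.87e-05), and lower under the value table's labels, with a log2 change of -2.003. NFYC had a log2 change of -0.37 ± 0.0944 (limma adjusted p = 0.0241). That call ended when all its probes were averaged (-0.14, adjusted p = 0.293). It also ended with the replicate number as a block (adjusted p = 0.0737) and with only the U-87MG arrays fitted (adjusted p = 0.0787). CXCL11 rose at least 14.7-fold by its representative probe, not well above background in the control, and 15.3-fold by another probe, above background on 1 of 2 control arrays. C6orf58 rose 59.5-fold, above background on 1 of 2 control arrays, and PDZK1IP1 at least 9.51-fold. The decreases below background were at least 88.2-fold for NFIB and for POU3F2, both transcription factor genes of neural development, and at least 83.5-fold for IGFBP5, a gene of an insulin-like growth factor binding protein. FABP7 fell at least 52.7-fold, HS6ST2 (heparan sulfate sulfation) 44.4-fold and GFRA1, a receptor gene for GDNF, 42.1-fold, each to below background. The neuronal membrane glycoprotein gene GPM6A fell at least 39.9-fold and DPYSL5 at least 37.7-fold. Under normexp the log2 changes were smaller than these bounds, at -2.739 for NFIB, -2.391 for POU3F2 and -2.815 for IGFBP5. None of these was called there (limma adjusted p = 0.0775, 0.087 and 0.0663).

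By camera, 3 lists were higher and 3 lower in U-87MG. Of 35 NF-kB target genes, 32 rose and 0 fell (33 and 0 adjusted over the list alone), with a mean log2 change of 2.5 (camera adjusted p = 7.12e-26; adjusted p = 0.0273 with an estimated correlation). CXCL8 rose 32.0-fold (50.1-fold or 20.4-fold without mimic replicate 1 or 2), CSF2 33.3-fold and IL1B 14.2-fold. Of 30 interferon-response genes, 27 rose and 0 fell, over the list alone too, with a mean of 1.46 (adjusted p = 1.42e-19; adjusted p = 0.0273 with an estimated correlation). OASL rose 6.96-fold, MX2 4.67-fold and MX1 2.65-fold, and XAF1 at least 2.87-fold. Among the protease, adhesion and angiogenesis genes, 18 rose and 5 fell of 33 (19 and 5 over the list alone; mean 0.518, adjusted p = 0.000166; adjusted p = 0.154 with an estimated correlation). MMP9 rose 8.52-fold, MMP1 3.25-fold and MMP13 1.54-fold. Cholesterol genes fell in 17 of 25 cases and rose in 1 (18 and 1 over the list alone; mean -0.582, adjusted p = 0.000305; adjusted p = 0.154 with an estimated correlation). DHCR7 fell 1.81-fold, MVK 1.56-fold and MSMO1 1.26-fold. Of 34 DNA replication genes, 17 fell and 1 rose (17 and 2 over the list alone; mean -0.283, adjusted p = 0.00534; adjusted p = 0.223 with an estimated correlation). E2F2 fell 1.87-fold, and MCM6 and TYMS 1.45-fold.

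Of 22 glial and neural progenitor genes, 14 fell and 3 rose in U-87MG (14 and 4 over the list alone), with a mean of -1.03 and a median of -0.695, or -0.843 with dim genes at their bound (adjusted p = 0.0109; adjusted p = 0.154 with an estimated correlation). SOX2, a neural stem cell factor, fell 12.3-fold, PDGFRA 3.50-fold and S100B at least 5.27-fold. Without U-87MG mimic replicate 2 this list was not called (adjusted p = 0.0772), and its mean was -0.0896 under normexp, where the median of all genes was 0.278. The mitotic list was not called (2 rose and 11 fell of 30, mean -0.179, adjusted p = 0.213), and neither were the stress list (7 and 9 of 27, adjusted p = 0.449) and p53 targets (3 and 7 of 25, adjusted p = 0.518). Markers of other cell types (4 and 3 of 19) had an adjusted p of 0.289. TGF-beta genes (9 and 10 of 35), miRNA pathway proteins (1 and 3 of 14) and hypoxia genes (4 and 6 of 27) had one of 0.841, and for hypoxia genes camera pointed up and the mean of -0.296 down. Under normexp 1232 genes were higher and 1394 lower, 9 of the 10 largest decreases (all but CXCL14) lost the call, and so did the protease list, though its mean was 0.588 (adjusted p = 0.0608), while the mitotic, stress and hypoxia lists were called lower (adjusted p = 3.85e-06, 0.0213 and 0.0225). Counts fell to 1887 higher and 3432 lower without U-87MG control replicate 1, 2219 and 3784 without control replicate 2, and 1393 and 2918 when only the U-87MG arrays were fitted.

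**Figure D2:**
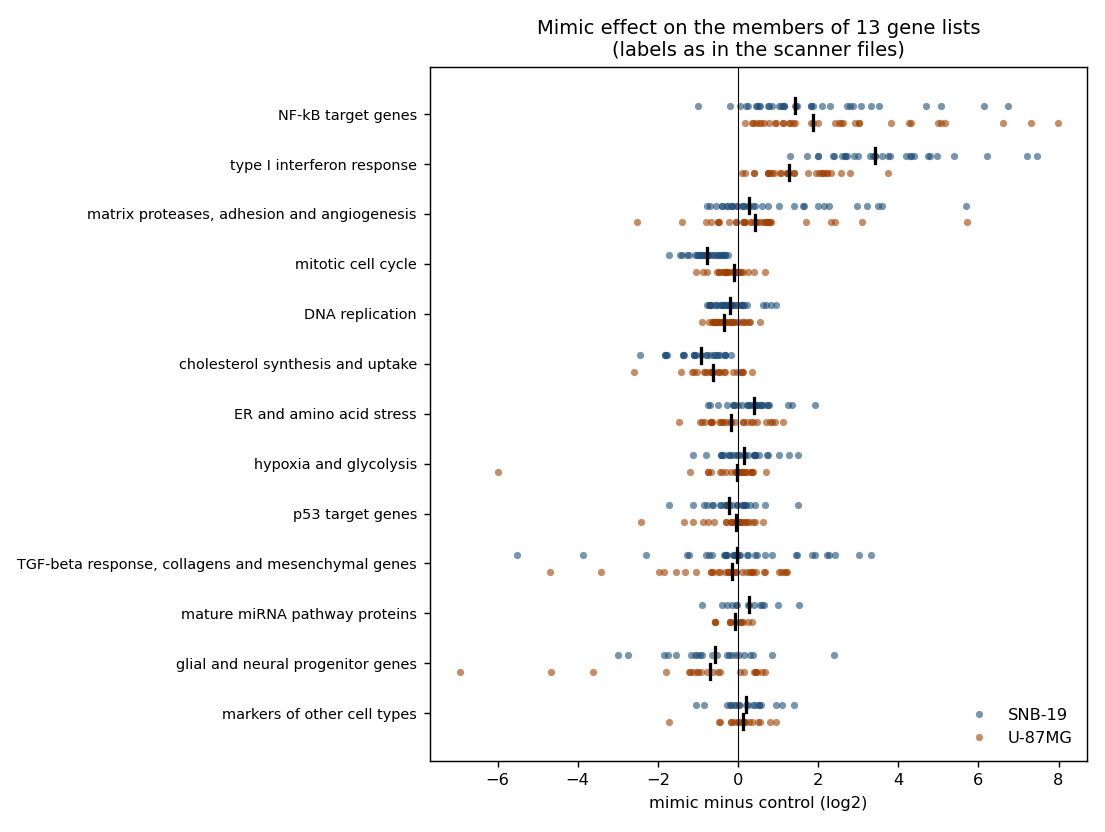
Mimic effect (horizontal axis, log2 of mimic over control as labelled in the scanner files) on each measured member of the 13 gene lists, 1 point per gene, with SNB-19 above U-87MG in each row and black bars at the medians. The medians of NF-kB target genes were 1.41 and 1.87 and those of interferon-response genes 3.43 and 1.27 in SNB-19 and U-87MG; with the value table's labels all directions turn.

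The mean of the effects in both lines asked what changed on average. By fitted values, CSF3 led the named increases and CXCL14 the named decreases on the arrays labelled mimic. CSF3 rose 202-fold on average, MMP3 51.9-fold, C3 30.5-fold, SAA1 29.1-fold and CXCL8 28.7-fold. CXCL11, CCL20, CXCL10, RSAD2 and SLCO2B1 completed the 10 largest, each not well above background on its representative probe in at least 1 control group. A2M, the gene of a protease inhibitor, fell 17.7-fold in SNB-19 and at least 20.0-fold in U-87MG, C6orf15 23.2-fold and at least 29.4-fold, and the transporter gene SLC47A2 16.0-fold and at least 11-fold. GPM6A fell 8.70-fold in SNB-19, HS6ST2 5.19-fold and IGFBP5 1.85-fold, beside their larger U-87MG decreases, and POSTN in U-87MG at least 5.59-fold. The POSTN bound holds for the main processing only. Under normexp POSTN had a log2 change of -1.994 in SNB-19 and -0.8209 in the mean (limma adjusted p = 0.14 and 0.318). These 2 values leave no decrease in U-87MG. In all, 5141 genes were higher and 6975 lower of 24853 tested (limma), 775 and 1380 of them by at least 2-fold, and the reverse with the labels turned. The SE was 0.0636 to 0.362 among the 20 largest changes, with adjusted p of at most 4.48e-05. NFKBIA was higher by 1.51 ± 0.0654 (adjusted p = 1.61e-05), and NFYC had a change of -0.12 ± 0.0668 (adjusted p = 0.171).

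In the mean effect, 33 of 35 NF-kB target genes rose and 0 fell, over the list alone too (mean 2.17, camera adjusted p = 2.49e-22; adjusted p = 0.0368 with an estimated correlation), and all 30 interferon-response genes rose (mean 2.58, adjusted p = 1.42e-24; adjusted p = 0.0343 with an estimated correlation). The other called lists lost their calls with an estimated correlation. Of these, 16 of 33 protease genes rose and 6 fell (mean 0.717, median 0.198, camera adjusted p = 0.000278, or 0.121 with an estimated correlation). Mitotic genes fell in 25 of 30 cases and rose in 0 (27 and 0 over the list alone; mean -0.491, adjusted p = 7.95e-08; adjusted p = 0.071 with an estimated correlation). Cholesterol genes fell in 23 of 25 cases and rose in 0 (mean -0.793, adjusted p = 5.24e-09; adjusted p = 0.066 with an estimated correlation). DNA replication genes fell in 20 of 34 cases and rose in 3 (mean -0.224, adjusted p = 0.00948; adjusted p = 0.229 with an estimated correlation); CHAF1B fell 1.44-fold. Glial genes fell in 12 of 22 cases and rose in 4 (mean -0.827, adjusted p = 0.0116; adjusted p = 0.121 with an estimated correlation). The stress and TGF-beta lists (adjusted p = 0.334 each), hypoxia and miRNA pathway lists (0.493 each), p53 targets (0.185) and markers of other cell types (0.204) were not called. Camera pointed up where the mean was down for hypoxia (-0.071, median -0.00322) and TGF-beta genes (-0.0946, median 0.0805). Lists without a call still held changed genes. Of the hypoxia list ADM rose 2.81-fold in SNB-19 and had a log2 change of 0.00474 in U-87MG (adjusted p = 0.966), LOX rose 1.59-fold on average and MXI1 fell 1.92-fold. BTG2, DDB2 and FDXR, p53 targets, fell 2.89-fold, 1.63-fold and 1.62-fold. The inhibitor-of-differentiation genes ID2 and ID1 rose 4.68-fold and 2.89-fold and the collagen gene COL1A2 fell 4.21-fold. The microprocessor gene DGCR8 and the exportin gene XPO5 rose 2.88-fold and 2-fold in SNB-19 and were not called in U-87MG (log2 changes of 0.0401 and 0.253, adjusted p = 0.762 and 0.0632). PRKRA and AGO4 fell 1.65-fold and 1.34-fold on average, AGO4 with a call in U-87MG only (adjusted p = 0.0614 in SNB-19). Among markers of other cell types VWF, CSF1R and CD68 rose 1.93-fold, 2.15-fold and 1.55-fold on average, CD68 with a call in SNB-19 only (adjusted p = 0.131 in U-87MG), and EPCAM fell 1.69-fold. Under normexp 2206 genes were higher and 2428 lower, the p53 list was called lower (adjusted p = 0.0227), and 9 genes picked by the naming rule lost the call (among them POSTN, SLC47A2, IGFBP5, EGLN3, GDF15, AGO4, S100B and EPCAM); the glial list lost it without U-87MG mimic replicate 2 (adjusted p = 0.0568), and its mean was -0.314 under normexp, where the median of all genes was 0.154.

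The difference between the lines, tested as the U-87MG effect minus the SNB-19 effect, asked where the mimic acted differently. Interferon-response genes rose less in U-87MG, and IGFBP5, ID4 and EGLN3 fell below background in U-87MG and stayed above it in SNB-19. Of 30 interferon-response genes, 29 had a lower effect in U-87MG and 0 a higher one (30 and 0 over the list alone), with a mean difference of -2.24 (camera adjusted p = 3.65e-18; adjusted p = 0.0607 with an estimated correlation). MX1 rose 74.8-fold in SNB-19 and 2.65-fold in U-87MG. IGFBP5 fell 1.85-fold in SNB-19 and at least 83.5-fold in U-87MG. Under normexp the differences were much smaller, at -1.923 for IGFBP5, -0.8363 for ID4 and -0.5401 for EGLN3. None of these was called there (limma adjusted p = 0.291, 0.553 and 0.707). In all, 4013 genes had a higher and 5189 a lower effect in U-87MG, of 24853 tested (limma), and the reverse with the labels turned. The SE was 0.132 to 1.02 among the 16 named largest differences, with adjusted p of at most 0.00703.

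NFKBIA rose more in U-87MG, by 0.96 ± 0.131 on the log2 scale (limma adjusted p = 0.00314), and NFYC differed by -0.50 ± 0.134 (adjusted p = 0.0299). The NFYC call ended when all its probes were averaged (-0.26, adjusted p = 0.185). It also ended with the replicate number as a block (adjusted p = 0.0872) and with no filter on dim probes (adjusted p = 0.0552). CXCL1 rose 7.34-fold in SNB-19 and 98.6-fold in U-87MG. The other 7 named genes with a higher effect in U-87MG were below background in at least 1 group: FLT3, COL3A1, CRTAM, ZPLD1, CDH19 and GIMAP1, which fell in SNB-19, and UGT2B7, below background in both SNB-19 groups. COL3A1, a collagen gene, fell at least 5.72-fold in SNB-19, with a log2 change of 0.27 in U-87MG (adjusted p = 0.483). Among named genes with a lower effect in U-87MG, the neurofilament gene NEFL rose 1.75-fold in SNB-19 and fell at least 15.8-fold in U-87MG by its representative probe, not well above background there; another probe, above background on all 8 arrays, fell 2.39-fold in U-87MG (adjusted p = 0.0133) and had a log2 change of 0.311 in SNB-19 (adjusted p = 0.379). DOK7 and ID4 rose 3.94-fold in SNB-19 and fell at least 6.11-fold and 4.39-fold in U-87MG. Under normexp the DOK7 difference was -0.7715 (limma adjusted p = 0.593). EGLN3, an oxygen-sensing hydroxylase gene, fell at least 16.9-fold and AUTS2, above background on 1 of 2 U-87MG mimic arrays, 58.5-fold in U-87MG, with log2 changes of -0.03 and 0.13 in SNB-19 (adjusted p = 0.87 and 0.664). KRTAP1-5 had a change of 0.46 in U-87MG (adjusted p = 0.0838), and CXCL14 fell in both lines. The p53 target gene GDF15 rose 2.84-fold in SNB-19 and fell 5.33-fold in U-87MG.

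Mitotic genes had a higher effect, meaning a smaller decrease, in U-87MG in 18 of 30 cases and a lower one in 0 (mean difference 0.624, adjusted p = 8.78e-08; adjusted p = 0.134 with an estimated correlation). Cholesterol genes had a higher effect in 14 of 25 cases and a lower one in 2 (mean 0.422, adjusted p = 0.00296; adjusted p = 0.266 with an estimated correlation), and NF-kB target genes in 16 of 35 and 5 (mean 0.664, adjusted p = 0.00138; adjusted p = 0.266 with an estimated correlation). Stress genes had a lower effect in 12 of 27 cases and a higher one in 1 (mean -0.466, adjusted p = 0.00371; adjusted p = 0.266 with an estimated correlation), and TGF-beta genes in 17 of 35 and 6 (mean -0.454, adjusted p = 0.0239; adjusted p = 0.266 with an estimated correlation). Not called were the protease (adjusted p = 0.153), miRNA pathway (0.244), hypoxia (0.306), DNA replication (0.627), p53, glial and other-cell-type lists (0.631 each). For p53 targets the mean was -0.0567 with the median and camera up, and for glial genes the median was 0.0587 with the mean of -0.405 and camera down. Under normexp 886 genes had a higher and 1144 a lower effect, 15 of the 18 named genes lost the call (NFKBIA, NFYC and CXCL1 kept it), and so did the NF-kB list (mean 0.376, adjusted p = 0.268) and the cholesterol list (mean 0.422 as before, adjusted p = 0.0776), while the protease, DNA replication, hypoxia and miRNA pathway lists were called lower (adjusted p = 0.0106, 0.00315, 0.00331 and 0.0173). The TGF-beta list lost it without SNB-19 mimic replicate 1 (adjusted p = 0.079) or U-87MG mimic replicate 2 (adjusted p = 0.0561) and in the value table with its columns exchanged (adjusted p = 0.0588), and leaving out either SNB-19 control array or either SNB-19 mimic array brought the count of higher effects to between 2319 and 2465, and of lower ones to 3384 without SNB-19 mimic replicate 1.

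The effects in the 2 lines, which share no array, were positively related. Across 24853 genes, which are not independent replicates, Pearson's r of the log2 changes was 0.413 and Spearman's rho 0.294, values that do not turn with the labels. Both lines called 5707 genes, and 4370 of them (76.6%) changed in the same direction. Higher in both were 1534 genes, among them CSF3, CXCL10 and MMP3, where independent lists would share 792.9. Lower in both were 2836, among them CXCL14, MVK and FABP7, where 1512 would be shared. Opposite calls were fewer than for independent lists: 865 genes were higher in SNB-19 and lower in U-87MG (1299.7 if independent), GDF15 among them, and 472 the other way (922.4). Under normexp r was 0.2406, with 408 genes higher and 469 lower in both. With only the arrays compared in each fit, 847 were higher and 1790 lower in both, and without U-87MG control replicate 1, 976 were higher in both.

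**Figure D3:**
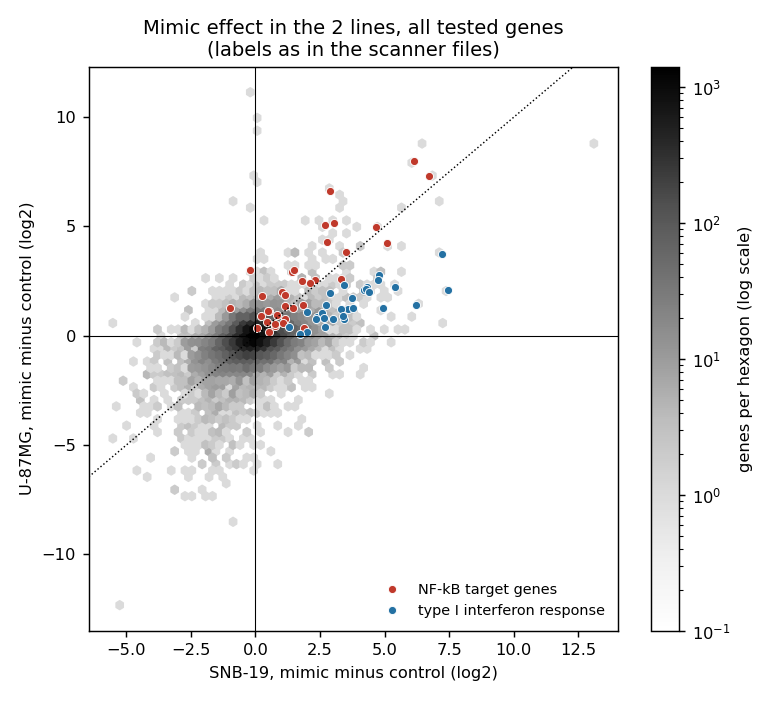
Log2 of mimic over control, as labelled in the scanner files, in SNB-19 (horizontal axis) and U-87MG (vertical axis) for all tested genes, shaded by genes per hexagon on a log scale, with the dotted line at equal effects. Red points are NF-kB target genes and blue points interferon-response genes, most of which lie below the line (29 of 30 called lower in U-87MG by the test of the difference); with the value table's labels both axes turn.

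The comparison of the lines on the arrays labelled control described their background. CD69, an activation antigen gene, was 15.6-fold lower in U-87MG, and the adhesion gene VCAM1 at least 4.03-fold lower. UCA1 was 12.4-fold higher in U-87MG and TBC1D25 10.3-fold. The guanine exchange factor gene KALRN was at least 2.43-fold higher by its representative probe, not well above background in SNB-19, while another probe, above background only in the SNB-19 control, had a log2 difference of -0.251 (adjusted p = 0.601). In all, 8098 genes were higher and 6216 lower in U-87MG, of 24855 tested (limma, 2 arrays per group), 1920 and 2063 of them by at least 2-fold. Among the 16 genes picked by the naming rule the SE of the log2 difference was 0.0762 to 1.27 and the adjusted p at most 0.0192. The apolipoprotein L gene APOL6 was 32.4-fold higher by its representative probe, but its probes disagreed and their mean had a log2 difference of 0.32 (adjusted p = 0.0501). Below background in SNB-19 were SH2D3C (at least 10.2-fold higher in U-87MG), STRA8 (5.4-fold), MED18 (4.18-fold) and the keratin gene KRT6B (3.70-fold). Below background in U-87MG were N4BP2L1 (at least 7.13-fold lower), PDZK1IP1 (6.75-fold), FLT3 (5.80-fold), KLRK1 (4.35-fold) and TECRL (3.50-fold). Under the value table's labels the other 4 arrays make this comparison, and 3931 of 14314 calls, 6 of the 16 genes picked by the naming rule among them, then have the opposite sign (r of the log2 differences across genes 0.3801). Under normexp 3687 genes were higher and 2104 lower and 12 of the 16 lost the call (all but APOL6, UCA1, TBC1D25 and CD69), and STRA8 and SH2D3C lost it without single control arrays (adjusted p up to 0.0795). Without U-87MG control replicate 1 or 2 their bounds were 1.58-fold or 18.5-fold for STRA8 and 19.6-fold or 5.28-fold for SH2D3C.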

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

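All tests of explanations in this part were chosen after the results were seen. Directions follow the scanner files' labels, and those of mimic effects turn, with their signs, under those of the value table.

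The value table and the scanner files give opposite treatment labels. All 8 columns of the table match the scanner file of the other treatment with the same line and replicate number, which is consistent with an exchange of labels in one of the sources. Other hybridisations or another way of processing are argued against by the lowest best correlation of 0.9999. Which source is right stays open: 0 probes carry the gene symbol of miR-30e itself, and the level of no other gene was used to decide.

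The test of the difference between the lines found 9202 genes whose mimic effect differed, as U-87MG minus SNB-19 on the log2 scale. For NFKBIA the difference was 0.96 and for NFYC -0.50. Among genes with the largest higher effect in U-87MG it was 5.92 for FLT3, 4.66 for CRTAM, 4.13 for COL3A1, 3.81 for UGT2B7, 3.75 for CXCL1, 3.73 for ZPLD1, 3.63 for GIMAP1 and 3.62 for CDH19. Among those with the largest lower effect it was -7.76 for IGFBP5, -6.94 for CXCL14, -6.88 for KRTAP1-5, -6.78 for NEFL, -6.36 for DOK7, -6.29 for ID4, -6.00 for AUTS2 and -5.97 for EGLN3. All but NFKBIA, NFYC and CXCL1 of these were not well above background on the representative probe in at least 1 array, so their values are fitted values and no bounds. The mean difference was 0.664 for NF-kB target genes, -2.24 for interferon-response genes, 0.624 for mitotic genes, 0.422 for cholesterol genes, -0.466 for stress genes and -0.454 for TGF-beta and mesenchymal genes; none of the 6 lists kept its call with an estimated correlation (adjusted p = 0.0607 to 0.266).

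A set of 85 genes had a representative probe not well above background on the U-87MG mimic arrays alone, with a fitted level over 8-fold below each other group. In a single other group 5, 0 and 2 genes were low. Other probes of these genes were not used: NEFL is in the set, though another of its probes was above background on all 8 arrays. Lower sensitivity of the U-87MG mimic arrays is argued against by 98.6% of 3401 other genes of like control level that stayed above background there. Other cells sharing nothing with SNB-19 are argued against by the 72 of the 85 genes (84.7%) also called lower in SNB-19. That share was 25.6% of the 21860 genes above background in the other 3 groups. On the other side, 4 genes of the set were called higher in SNB-19, ID4 and NEFL among them. The decrease in SNB-19 cannot argue against other cells on the mimic arrays of both lines, which could lower the set in SNB-19 too. An effect of the treatment in both lines that goes further in U-87MG may account for much of the set, though not for these 4 genes. The median log2 change of the set in SNB-19 was -1.43. That median restates the decrease in SNB-19 and is no separate test. Other cells on both sets of mimic arrays stay open, and so does slide position, because it follows the treatment in both lines. Under normexp the calls of 9 of the 10 largest U-87MG decreases ended, as IGFBP5 went from -8.65 to -2.82 (adjusted p = 0.0663), so the size of these decreases depends on how background is handled.

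Interferon-response genes rose less in U-87MG than in SNB-19, a list call that was lost with an estimated correlation and 4 degrees of freedom (camera adjusted p = 0.0607). A compression of all changes on the U-87MG arrays is argued against by 16 of 35 NF-kB target genes with a higher effect in U-87MG, against 5 with a lower one. This count replaced the list's mean difference as the test after both were seen. That list's camera call was lost with an estimated correlation (adjusted p = 0.266) and under normexp (adjusted p = 0.268). Other lists went the other way. Mitotic genes had a smaller decrease in U-87MG in 18 of 30 cases and a larger one in 0, and 14 of 25 cholesterol genes had a higher effect, against 2 with a lower one. Compression of part of the changes stays open. A list already raised in the U-87MG control is argued against by a median control level of -1 (log2, U-87MG minus SNB-19), with 26 of 30 members lower and 1 higher; under the value table's labels the other 4 arrays make this comparison, which was not tested. A difference between the lines in how they respond may remain, but 0 slides held both lines, so line and slide cannot be told apart.

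Of 18 splits of the 8 arrays with 2 arrays of each line on either side and line kept as a term, 1, the real one, called as many genes as the mean mimic effect (12116). With 18 splits no share under 0.05 can be had. The highest other split called 9202; it sets the SNB-19 mimic arrays with the U-87MG control arrays, and its contrast is the difference between the lines.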

How the results depend on the processing

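The value table with its columns exchanged and the SNB-19 fit without the U-87MG mimic arrays were chosen after seeing the data; the other alternatives were planned. Over all alternatives except the value table read by its own column names, 2433 of 2508 values of named genes kept direction and call, 75 lost the call (52 under normexp) and 0 reversed; of 741 list values 682 kept both, 26 lost the call, 30 gained one and 3 reversed. NFKBIA stayed called, at 0.97 to 1.09 in SNB-19, 1.92 to 2.06 in U-87MG, 1.46 to 1.55 in the mean and 0.89 to 1.03 for the difference (highest adjusted p 0.0258). NFYC lost its call in 6 of 18 alternatives in U-87MG and 9 of 17 for the difference (highest adjusted p 0.293 and 0.185). Quantile normalization kept 97.3%, 91.5% and 94.9% of the calls in SNB-19, U-87MG and the mean, and 97.7%, 97.2% and 97.0% were kept with the value table's columns exchanged. The DNA replication list in SNB-19 gained a call under quantile normalization (adjusted p = 0.0358) and normexp (adjusted p = 0.0175). No scaling moved the share of higher calls by over 10 percentage points. Genes near background are what signal over background limits.

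Read by its own column names the value table turned nearly all mimic effects. Higher and lower counts were 6074 and 5637 in SNB-19, 5728 and 3823 in U-87MG, 6633 and 5388 in the mean, and 5237 and 4026 for the difference, and NFKBIA was at -1.045, -2.003, -1.524 and -0.9579. The cause is the exchange of labels. Signs turned for 22 of 22 named genes in each line, 70 of 70 in the mean and 18 of 18 for the difference, and for 11722 of 11723, 9596 of 9600, 12115 of 12116 and 9195 of 9202 calls. For the lines 3931 of 14314 calls turned, because other arrays make that comparison; list tests were not repeated with these labels.

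Normexp kept 34.2%, 24.7% and 37.1% of the calls. Counts were 2043 higher and 1991 lower in SNB-19, 1232 and 1394 in U-87MG, 2206 and 2428 in the mean, 886 and 1144 for the difference and 3687 and 2104 for the lines; r was 0.2406, with 408 and 469 genes shared higher and lower. Lists lower in U-87MG were 6, mitosis among them (adjusted p = 3.85e-06), and for the difference 1 was higher and 7 lower; camera pointed down for the hypoxia list in U-87MG, where it had pointed up without a call, while the list's mean was negative both times (-0.296 and -0.158), and the glial list, still called, went from -1.03 to -0.0896 in U-87MG and from -0.827 to -0.314 in the mean. The median of all genes moved to 0.278 in U-87MG, 0.154 in the mean, 0.346 for the difference and 0.163 for the lines, so normexp directions are relative to that. The cause was not tested.

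With only the arrays compared, U-87MG had 1393 higher and 2918 lower genes, and 847 and 1790 were shared. In that U-87MG fit the spread came from the U-87MG arrays alone. Replicates differed most in the U-87MG mimic group (SD of the log2 difference 0.385, against 0.192 to 0.251 in the other groups). The main fit shares 1 spread per gene over all 4 groups, so its U-87MG SEs may be too small and its U-87MG counts too high. The replicate block gave 2393 higher genes in U-87MG and 2605 for the difference and changed no other count by over 1.5 times. With this block 80.7%, 67.4% and 81.6% of the calls in SNB-19, U-87MG and the mean were kept. Deviations of same-numbered arrays correlated at -0.0568 in SNB-19 and -0.0557 in U-87MG, so the numbers show no pairing. With an estimated correlation 2 lists were higher in SNB-19, 0 lower in U-87MG, 0 lower in the mean, and 0 and 0 higher and lower for the difference. By fry 8 and 5 lists were higher and lower in SNB-19, 9 lower in U-87MG, 7 higher in the mean and 9 lower for the difference, with hypoxia in U-87MG at -0.296 and p53 targets for the difference at -0.0567, where camera pointed up; fry does not compare a list with other genes. With only probes above background on all 8 arrays, genes without such a probe have no value. The TGF-beta list lost its call for the difference in the value table with its columns exchanged (adjusted p = 0.0588).

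Leaving out each array in turn gave 3811 to 6362 higher and 4270 to 7834 lower genes in SNB-19, 1887 to 4926 and 3432 to 7701 in U-87MG, 3997 to 5975 and 5508 to 8422 in the mean, 2319 to 5470 and 3384 to 7003 for the difference and 5936 to 9174 and 4511 to 7312 for the lines. r was 0.365 to 0.437, with 976 to 1860 genes shared higher and 1932 to 3588 lower. The lone array was assumed to vary like the other groups. U-87MG control arrays 1 and 2 gave the lowest U-87MG counts. Lists higher and lower were 4 and 3 in SNB-19, 3 and 2 to 3 in U-87MG, 3 and 3 to 4 in the mean and 3 and 2 to 3 for the difference. Without both U-87MG mimic arrays SNB-19 had 6362 higher and 7834 lower genes, with 4 and 3 lists. Seed matches of miR-30e* were not run, because no 3′ UTR annotation was used here, and neither was the slide as a block.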

Other observations

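The tests in this part were chosen after the data were seen, over 249 families of at least 8 genes that share a symbol prefix. Directions follow the scanner files' labels and turn under those of the value table. In the mean effect, 18 of 21 HLA genes, which encode antigen-presenting proteins and related pseudogenes, rose and 0 fell (median log2 change 0.72, camera adjusted p = 1.52e-07; adjusted p = 0.615 with an estimated correlation). HLA-DQB1 rose by 2.00 ± 0.0789 (SE), HLA-DRB5 by 1.57 and HLA-B by 0.83. Probes of such close relatives were not checked for cross-hybridisation. Of 10 metallothionein genes, which encode metal-binding proteins, 8 rose and 1 fell (median 0.827, adjusted p = 0.0048; adjusted p = 0.715 with an estimated correlation). MT1B rose by 0.99 and MT1E by 0.94, and MT1F had a change of -1.60, with -3.07 in U-87MG and -0.12 in SNB-19 (adjusted p = 0.803).

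Of 8 aldo-keto reductase genes (AKR), 7 fell and 1 rose (median -0.499, adjusted p = 0.0338; adjusted p = 0.715 with an estimated correlation). AKR1C3 fell by 3.67 ± 0.0657, AKR1C1 by 3.30 and AKR1B10 by 2.99 on the log2 scale, and AKR1B1 rose by 0.63. Of 14 protocadherin beta genes, neural adhesion molecules, 11 fell and 0 rose (median -1.34, adjusted p = 0.000743; adjusted p = 0.715 with an estimated correlation), but the median under normexp was 0.0997, where that of all genes was 0.154. PCDHB9 and PCDHB10, not well above background on the U-87MG mimic arrays, had fitted changes of -2.87 and -2.52 in SNB-19. PCDHB4, PCDHB5, PCDHB12 and PCDHB18P, counted among those that fell, were well above background on both arrays in the SNB-19 control group alone. They were not well above background in either U-87MG group, so their U-87MG changes compare signals near background. For HLA, metallothionein and AKR genes the median kept its sign under quantile, median and normexp scaling. Genes of RNA helicases and ribosome assembly also passed in the mean effect with the preset correlation. Of 31 DDX genes, 14 were higher and 2 lower (median 0.162, camera adjusted p = 0.0217, or 0.715 with an estimated correlation). Of 11 UTP genes, 7 were higher and 0 lower (median 0.244, camera adjusted p = 0.0221, or 0.715 with an estimated correlation). Neither DDX nor UTP passed in a single line (camera adjusted p in SNB-19 and U-87MG 0.0686 and 0.202 for DDX, 0.0588 and 0.0996 for UTP). Of 9 RRP genes 7 and of 16 DHX genes 9 were higher, and 0 lower (camera adjusted p = 0.0338 and 0.042, or 0.715 each with an estimated correlation). RRP passed in SNB-19 (camera adjusted p = 0.0299) and not in U-87MG (0.633), and DHX in neither line (0.291 and 0.0985). Further families that passed, such as CXCL, are not described here. AKR genes passed in U-87MG (camera adjusted p = 0.0475) and not in SNB-19 (0.0864).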
